A study of Homo sapiens with 27 samples.

How the data were processed

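RNA was measured in 27 pinch biopsies of intestinal mucosa from non-IBD control subjects. Per the labels' protocols, biopsies were taken at colonoscopy with cold forceps, snap-frozen, extracted with Trizol and column-purified. RNA was labelled with Cy3 for 1-colour Agilent arrays. All 27 biopsies carry the same disease state, so they form 1 group with no contrast. Sample titles carry 27 different control numbers, but the labels give no bowel segment, no donor and no number of donors. Every p-value therefore measures spread between biopsies, some of which can share a donor.

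The deposited scanner tables hold spot intensity, per the file headers, from Agilent Feature Extraction 10.7.3.1. Per the file headers, the processed signal is the background-subtracted and spatially detrended intensity, with no normalization between arrays. The deposited tables also hold flags of 0 or 1 per spot for signal well above background, saturation and outliers. The deposited series matrix holds log2 values with nearly equal distributions in every column, with column medians from 6.08 to 6.10. Each of its 27 columns correlated best, across probes, with its own array (r from 0.984 to 0.990). Its exact centring is not stated. The submitters' processing notes name limma 3.26.9 without stating its role.

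Each array carried 62976 spots, of which 58717 were not controls and stood for 42405 probes. Names came from the RefSeq table of assembly GRCh38.p14 by accession without version. A symbol was found for 25715 probes, and 8263 lincRNA, 2714 Ensembl and 4183 other probes stayed unnamed. The array design names genome build GRCh37, so no coordinates are given. A total of 78 probes for Y-linked or X inactivation genes were removed first.

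The processed signal was log2-transformed and the 75th percentile of each array was subtracted. Outlier spots were left out, control spots were left out, and spots of the same probe were averaged. A gene was called detected when a probe was well above background on at least 14 of the 27 arrays, and its brightest such probe stood for it. Saturated spots numbered 0. The number of arrays limits the precision of every value.

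A total of 30 gene lists with 445 entries were fixed before the data were examined, together with the tests, most alternative settings and the rule for naming genes. The lists cover pan-epithelial, ileal enterocyte, Paneth, colonocyte, distal colon, goblet, enteroendocrine, BEST4 and tuft, crypt base and proliferation genes. They cover plasma cell, B cell follicle, T and NK cell, macrophage and dendritic, and mast cell genes. They also cover acute inflammation, epithelial inflammatory response, interferon response, fibroblast and matrix, smooth muscle, endothelial, glia and neuron, and red blood cell genes. The remaining lists hold immediate early, heat shock, metallothionein, drug and bile acid handling, mitochondrial fuel use, IBD drug target and housekeeping genes. A 9-gene list of M cell and follicle-associated epithelium genes was added later.

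The naming rule took the 25 detected genes with the largest SD. From each list it took up to 4 members with the largest SD, and members not well above background on any array. From each score it took the 8 largest positive and 8 largest negative slopes past adjusted p 0.05 outside the list. HLA genes, immunoglobulin and T cell receptor segments, and a short fixed set of genes with common copy number or expression variants were left out of naming (47 genes). Genes outside that set were not screened for such variants, so a named gene can carry one. Genes without a symbol were not named. A few genes that meet the rule are left out of the text, though counts include them.

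The median SD of each list was set against 10000 random lists of the same size matched on signal. A list score was the mean of the gene-centred log2 signal of its detected members. Scores were compared by Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples, adjusted by Benjamini-Hochberg over all pairs. A score was treated as separate clusters when mclust 6.1.1 preferred 2 components by more than 10 BIC units with at least 3 biopsies in each. Genes that track a score were tested with limma 3.58.1 (lmFit and eBayes with a trend) under R 4.3.3, as a slope on the score. Slopes are printed per SD of the score unless given per log2 unit of it. Genes that differ between slides were tested with limma's moderated F test. Benjamini-Hochberg adjustment covered all detected genes outside the list. Tables were read with the R package data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

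The fits on 4 scores and the slide test were tested on simulated data over 15257 genes, with 100 genes changed per size. The fit within distal colon clusters and the comparison with random lists were not simulated. For slopes of 1 SD the test recovered 87 genes on the pan-epithelial score, 86 on the B cell follicle score, 89 on the ileal enterocyte score and 77 on the acute inflammation score. For slopes of 0.5 SD it recovered 16, 10, 12 and 7, with 5, 6, 10 and 3 false calls over both sizes. The slide test recovered 36 genes shifted by 2 SD on a slide and 3 shifted by 1 SD, with 3 false calls. Simulated genes were independent of each other, unlike the measured genes, so these false calls do not bound those in the real counts. With the measured genes, a permuted pan-epithelial score called up to 910. The permutation test of list pairs gave p under 0.05 in a share of 0.04 of 200 trials with no relation and in every trial at a planted r of 0.7.

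The alternative settings chosen first were normexp background correction (offset 50) with quantile normalization, the series matrix values, other filters on dim probes, the mean of probes, z scores, removal of extreme biopsies, covariates, slide as a block and a robust variance model. The mean signal is not among the file columns, so normexp used the median signal. Alternatives added after the data were seen left out 3 doubted arrays (the lowest signal and 2 marked by the scanner software), left out each slide, removed slide means, or used array signal as a covariate. The separate IBD series was not used. Of the per-sample value columns, 0 were left unused in the deposited tables.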

Results

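The study collected 27 intestinal mucosa pinch biopsies from non-IBD control subjects, each measured on its own 1-colour array, as a reference for biopsies from IBD patients in another series. All biopsies belong to a single group, so the questions concern which genes the control mucosa gives signal for and how biopsies differ from each other. The arrays lay on 4 slides, with 3 arrays on slide 1 and 8 on each of slides 2, 3 and 4. Spots well above background numbered 32328 to 46383 per array (median 41222). The 75th percentile signal ranged from 100.5 to 714 with a median of 466. Correlations between arrays, taken across probes that are not independent replicates, ranged from 0.904 to 0.979.

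Control mucosa gave signal for genes of surface epithelium, and 14 of 20 ileal enterocyte genes were detected. The intestinal keratin KRT20 had a log2 signal, relative to the array's 75th percentile, of 4.48 ± 0.72 (SD, n = 27), and the intestinal transcription factor CDX2 one of 4.27 ± 0.45. The colonocyte genes AQP8, a water channel, and CEACAM7, an adhesion molecule of the surface epithelium, stood at 4.60 ± 1.08 and 5.67 ± 0.78. Fat-handling genes of that list were split: FABP2 was well above background on 25 arrays and the apolipoprotein APOA4 on 14. APOB, APOC3 and MTTP, which build lipid-carrying particles, were not well above background on any array, nor were the cobalamin receptor CUBN and the glucose carrier SLC2A2. FGF19, the bile acid-induced hormone of the ileum, was not well above background on any array either. Of 19659 named genes, 15257 (77.6%) were detected, 11678 (59.4%) on every array, and 1487 were never well above background.

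Genes of lymphoid follicles were among those that differed most between biopsies. The follicle genes FDCSP, TCL1A, CCL21, CXCL13, CCL19 and CR2 had SDs of 2.69, 2.63, 2.15, 2.15, 2.11 and 2.11 log2 units (n = 27 throughout). With normexp and quantile normalization these SDs were 1.64, 1.59, 1.55, 0.96, 1.85 and 1.13. The positional gene HOXD13 had an SD of 2.89 (1.62 with that normalization). DUOXA2, the maturation factor of an epithelial oxidase, had one of 2.14 (1.35 with that normalization), and the immediate early gene FOSB one of 2.60 (1.51). The glucuronidation enzyme UGT2B15 stood at 3.20 and the butyrophilin-like gene BTNL8 at 2.96, while a second BTNL8 probe gave 0.55. Neither gene was screened for copy number variants. CD177, a surface glycoprotein, had an SD of 2.23 (1.18 by its second probe), the chemokine CCL23 2.23, the proton pump ATP12A 2.17, PSCA 2.07 and the keratin KRT79 2.06. LGSN, GUCY1B2, TASOR2 and DDTL had SDs of 2.80, 2.28, 2.15 and 2.12. HNRNPM, PGAM4, COX5A, MKRN7P and TMEM109 had SDs of 2.46, 2.42, 2.37, 2.11 and 2.09, but within slides these were 0.40, 0.41, 0.24, 0.87 and 0.32. With normexp and quantile normalization UGT2B15 had an SD of 2.57, BTNL8 1.92, CD177 1.78, KRT79 1.68, PSCA 1.44, LGSN 1.23 and ATP12A 1.17. That of GUCY1B2 was 0.97, of DDTL 0.79, of TASOR2 0.76, of CCL23 0.75 and of MKRN7P 0.67.

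The median SD of all detected genes was 0.40 log2 units, and 827 genes (5.42%) exceeded an SD of 1. That count depended on processing: it was 124 with normexp and quantile normalization, 286 with the series matrix, 208 with probes above background on every array and 2197 without a filter. Repeated spots of a probe within an array had a median SD of 0.08 (999 probes), while E1A spike-in probes had one of 0.63 between arrays after scaling (6 probes). Where a gene had a second detected probe (3576 genes), the median correlation of both probes over biopsies was 0.371.

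The epithelial lists covered absorptive, secretory and dividing cells. The pan-epithelial list had all 20 genes detected and a median SD of 0.30, with KRT20 at 0.72, KRT8 at 0.55 (second probe 1.70) and the junction gene CLDN7 at 0.41. Colonocyte genes (17 of 18 detected) had a median SD of 0.63, led by CLCA4 at 1.17, MS4A12 at 1.11 and AQP8 at 1.08. Ileal enterocyte genes (14 of 20) had one of 0.85, with the regulator CREB3L3 at 1.54, the apolipoprotein APOA4 at 1.13 and the fatty acid carrier FABP2 at 1.11. Among Paneth genes (4 of 7, median 1.35), the lectin ITLN2 had an SD of 1.49 and the defensin DEFA6 1.39, and REG3G was never well above background. Distal colon genes (7 of 9, median 0.60) were led by HOXD13, HOXD10 at 2.05 and HOXD11 at 1.69. Goblet cell genes (14 of 14, median 0.57) included SPINK4 at 1.65 and RETNLB, a secreted antimicrobial protein, at 1.58. Enteroendocrine genes (13 of 17, median 0.62) included the hormones INSL5 and SST, both at 1.29. The BEST4 and tuft list (11 of 12, median 0.84) held the ion channel genes OTOP2 at 1.20 and BEST4 at 1.06. Crypt base genes (11 of 11, median 0.46) were led by OLFM4 at 2.04 and the stem cell receptor LGR5 at 0.85. Proliferation genes (20 of 21, median 0.52) were led by RRM2 at 1.20 and TOP2A at 1.01, which serve DNA synthesis and untangling.

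B cell follicle genes spread most widely of the 30 lists: 17 of 18 detected members had an SD above 1, and the list's median was 1.61. The B cell regulator PAX5 was not well above background on any array. Plasma cell genes (13 of 13, median 0.41) were led by FCRL5 at 0.78 and IRF4 at 0.76. In the T and NK cell list (21 of 21, median 0.73), the cytotoxic protein GNLY had an SD of 1.10 and the T cell surface gene CD5 0.93. Macrophage and dendritic genes (15 of 17, median 0.57) included the integrin ITGAX at 0.88 and the scavenger receptor CD163 at 0.61. Mast cell genes (8 of 10, median 0.72) included GATA2 at 0.88 and the tryptase TPSAB1 at 0.82. Acute inflammation genes (10 of 20, median 0.92) included the neutrophil chemokine CXCL3 at 1.38 and the calcium-binding S100A8 at 1.13. The epithelial inflammatory response list (13 of 20, median 1.22) held DUOX2 at 1.85, VNN1 at 1.69 and the matrix protease MMP3 at 1.60. In the interferon response list (19 of 21, median 0.73), the T cell chemokine CXCL9 stood at 1.44 and IFI44L at 1.25.

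Stroma and stress genes followed. Smooth muscle genes (10 of 12, median 0.88) were led by the filament gene DES at 1.52 and the myosin MYH11 at 1.08, and CASQ2 and PLN were never well above background. Within slides the smooth muscle median was 0.61, below metallothionein (0.73) and immediate early genes (0.72). Fibroblast and matrix genes (16 of 16, median 0.50) included FAP at 0.73, endothelial genes (12 of 14, median 0.54) CLDN5 at 0.72, and ERG was never well above background. Glia and neuron genes (11 of 13, median 0.58) included L1CAM at 1.28, and red blood cell genes (5 of 7, median 0.69) HBB at 0.78, with AHSP never well above background. Immediate early genes (12 of 14, median 0.79) included FOS at 1.53 and EGR1 at 1.25, and NR4A1 was never well above background. Metallothioneins (8 of 8, median 0.80) included MT1M at 1.16 and MT1G at 1.08, near-identical genes whose probes can share signal. Heat shock genes (10 of 10) had a median of 0.36, with HSPA6 at 0.70. Drug and bile acid handling genes (15 of 16, median 0.82) included the bile acid exporter subunit SLC51A at 1.67. Mitochondrial fuel use genes (11 of 12, median 0.36) included the carrier of short acids SLC16A1 at 0.76. IBD drug target genes (17 of 20, median 0.54) included JAK3 at 1.03 and OSMR at 0.97, and S1PR5 was never well above background. Housekeeping genes (12 of 12) had a median of 0.24.

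Against random lists matched on signal, 22 of the 30 lists had a median SD above the 95th percentile. The other 8 lists were plasma cell (percentile 94.7), IBD drug target (89.2), mitochondrial fuel use (82.1), heat shock (78.8), endothelial (76.0), pan-epithelial (59.5), glia and neuron (44.5) and housekeeping (2.92). These percentiles describe the biopsies at hand, since genes are not independent.

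**Figure D1:**
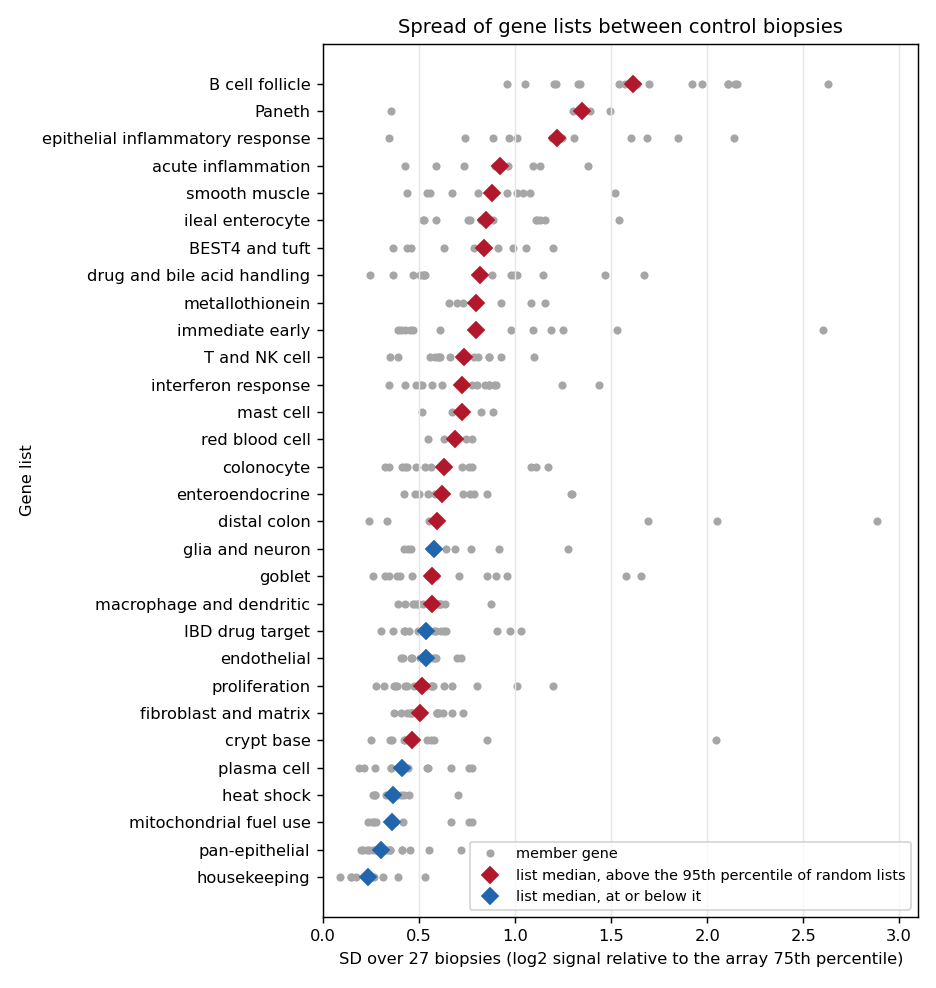
The SD of log2 signal over the 27 biopsies (x axis) is plotted for the 30 lists, with grey points for detected member genes and diamonds for medians, red above the 95th percentile of random lists and blue otherwise. The B cell follicle list has the highest median, 1.61, and the housekeeping list the lowest, 0.24.

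Several pairs of cell type scores were correlated between biopsies. Pan-epithelial and colonocyte scores rose together (r = 0.817, rho = 0.663), as did colonocyte and drug and bile acid handling scores (r = 0.743, rho = 0.677). Colonocyte scores, which mark mature absorptive cells, ran opposite to crypt base scores, which mark stem cells (r = −0.706, rho = −0.606). B cell follicle and T and NK cell scores rose together (r = 0.730, rho = 0.648), and both rose with the IBD drug target score, which holds cytokines and lymphocyte kinases (r = 0.729 and 0.780, rho = 0.717 and 0.776). Fibroblast and endothelial scores rose together (r = 0.784, rho = 0.797).

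Of 464 pairs tested, 406 over all biopsies and 58 within clusters of the distal colon score, 16 passed and 69 had an unadjusted p under 0.05. Of the 16, 13 were positive and 3 negative. For the pan-epithelial and colonocyte pair the permutation p of r was 1e-05, the smallest the permutations can give, that of rho 0.00022, and the adjusted p of r 0.00116. The same p of r and adjusted p held for the colonocyte and drug handling pair, the T and NK cell and IBD drug target pair, and the fibroblast and endothelial pair. Their permutation p of rho was 0.00017, 1e-05 and 1e-05. Colonocyte and crypt base scores had permutation p of 4e-05 for r and 0.00118 for rho (adjusted p of r 0.00265). B cell follicle and T and NK cell scores had 5e-05 and 0.00036 (adjusted 0.0029), and B cell follicle and IBD drug target scores 2e-05 and 5e-05 (adjusted 0.00186). Without the 2 biopsies farthest from the median of the first score, r was 0.702, 0.654, 0.787, 0.780, −0.744, 0.692 and 0.637 for these 7 pairs in the order given. On slides 2, 3 and 4 the first of them had r of 0.634, 0.757 and 0.764, and colonocyte and crypt base had −0.758, −0.836 and −0.757. B cell follicle and T and NK cell had 0.736, 0.886 and 0.615, the other 4 pairs lay between 0.523 and 0.951, and slide 1 held too few arrays for a value. Given the number of probes above background, the B cell follicle score lost its call with IBD drug targets (r = 0.549, adjusted p = 0.0666; 0.000773 to 0.0666 over all alternatives) and with T and NK cells (r = 0.574, adjusted p = 0.0524; 0.000773 to 0.0524). Given array signal the pair with IBD drug targets lost it too (r = 0.576, adjusted p = 0.0513), and the pair with T and NK cells kept it (r = 0.625, adjusted p = 0.0211).

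The other 9 pairs had absolute r from 0.576 to 0.711. Smooth muscle and endothelial scores had r = 0.70 (rho = 0.691, adjusted p = 0.00232) but 0.459, 0.30 and 0.90 on slides 2, 3 and 4, and the call was lost with scores centred within slides (adjusted p = 0.0616; 0.00206 to 0.0616 over all alternatives). Drug and bile acid handling rose with mitochondrial fuel use (r = 0.711, rho = 0.70, adjusted p = 0.00361; 0.000928 to 0.0565 over all alternatives), and proliferation ran opposite to T and NK cells (r = −0.646, rho = −0.641, adjusted p = 0.0135). Mitochondrial fuel use ran opposite to IBD drug targets (r = −0.640, rho = −0.553, adjusted p = 0.0135), which was lost given the array's signal (r = −0.336, adjusted p = 0.422; 0.00258 to 0.422 over all alternatives). Plasma cell and IBD drug target scores had r = 0.629 (rho = 0.637, adjusted p = 0.0193; 0.0106 to 0.0705 over all alternatives) but 0.167 on slide 4, and fibroblast and glia scores r = 0.576 (rho = 0.568, adjusted p = 0.0490) but −0.0286 on slide 3. Fibroblast and glia scores lost their call in 5 of 10 alternatives (adjusted p from 0.00174 to 0.102). Acute inflammation rose with immediate early genes (r = 0.663, adjusted p = 0.0200), though not by rank (rho = 0.450, adjusted p = 0.231). Acute and epithelial inflammatory scores had r = 0.591 (rho = 0.496, adjusted p = 0.0390; 0.00974 to 0.264 over all alternatives) and 0.407 without the 2 biopsies farthest from the median. Pan-epithelial and housekeeping scores had r = 0.599 (rho = 0.631, adjusted p = 0.0302; 0.0103 to 0.151 over all alternatives) but 0.137 on slide 3. On slides 2 to 4 the 5 pairs without a slide value here kept their sign, with the weakest r of −0.30 for proliferation and T and NK cells on slide 2.

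**Figure D2:**
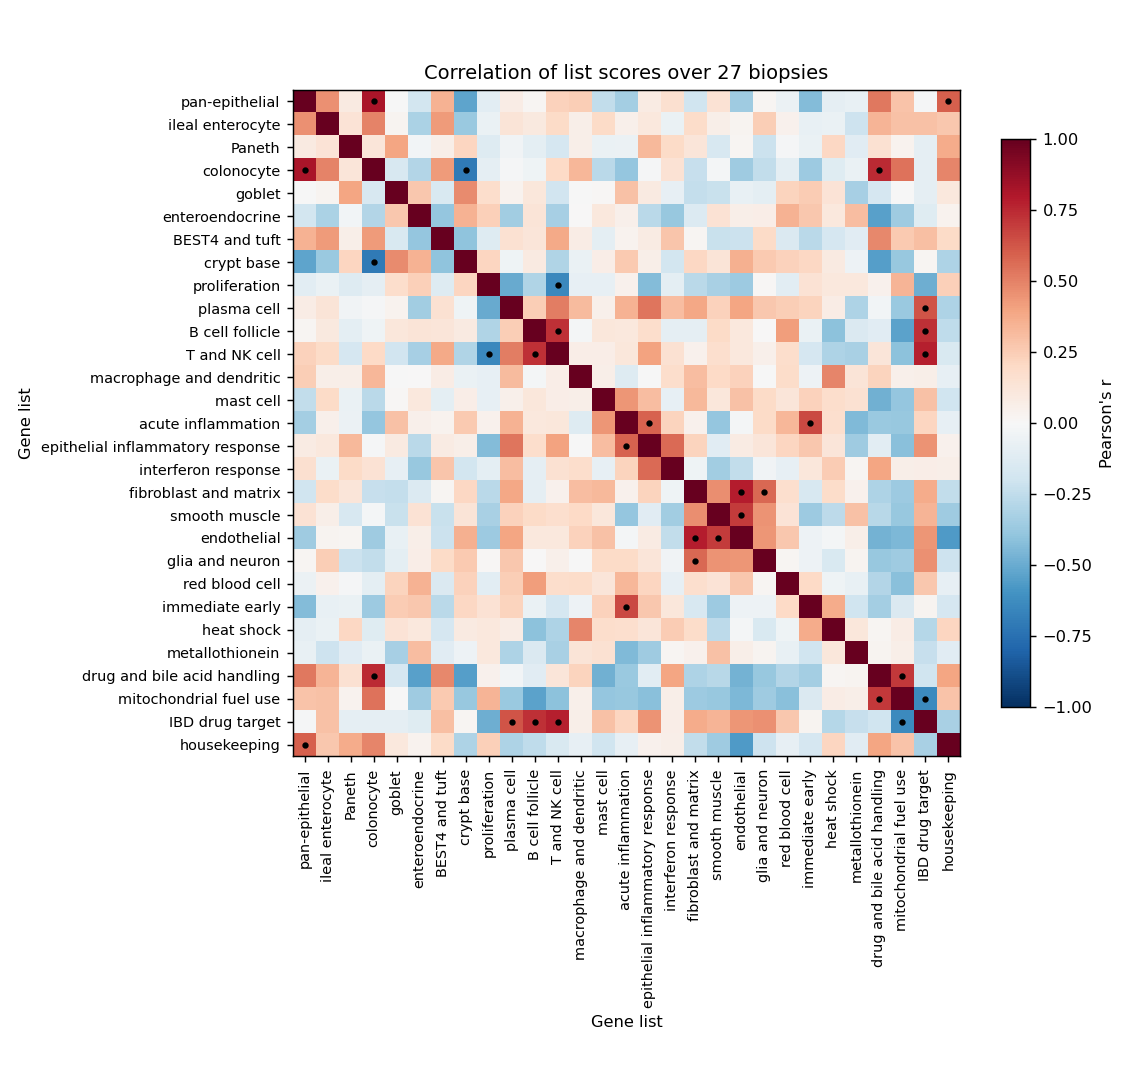
Pearson's r between list scores over the 27 biopsies is coloured from blue (negative) to red (positive), with dots on the 16 pairs past the test and the distal colon list left out because its scores fell into clusters. The darkest dotted square joins the pan-epithelial and colonocyte lists (r = 0.817).

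Slides, the only batch recorded for all arrays, separated many genes. COX5A, a subunit of the respiratory chain, had mean log2 signals of 2.09, 2.19, −2.50 and −2.62 on slides 1 to 4. The splicing factor HNRNPM had −0.43, −0.17, −5.03 and −5.16, and TMEM109 −0.60, −0.50, −4.72 and −4.58. PGAM4 had 1.11, 1.17, −3.30 and −3.91, and the histone gene H3C1, chosen after its values were seen, 2.36, 2.73, −0.82 and −1.04. For 64 genes slide explained more than 0.9 of the variance, and all 63 of these that could be named were higher on slides 1 and 2 than on slides 3 and 4. Their median difference was 2.0 log2 units. Smooth muscle scores also differed: −0.98 ± 0.36 (SD, n = 3), −0.47 ± 0.47, 0.33 ± 0.69 and 0.51 ± 0.58 (n = 8 each). Theirs was the only one of 30 list scores to pass a permutation test over slides (p = 0.0011 over 10000 permutations, adjusted p = 0.033).

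By limma's moderated F test, 2582 of 15257 genes (16.9%) differed between slides at adjusted p under 0.05. They included 6 of 10 smooth muscle, 5 of 15 macrophage and dendritic, 4 of 16 fibroblast and matrix, 3 of 20 pan-epithelial and 3 of 11 mitochondrial fuel use genes. By the same limma test 0 of 20 proliferation, 0 of 18 B cell follicle, 0 of 17 colonocyte and 0 of 12 endothelial genes passed. Over all genes 4562 had an unadjusted p under 0.05. Without slide 2 the count was 606, and without slide 4 it was 1251. The labels do not state how biopsies were placed on slides. Control numbers in the sample titles rose from slide 2 to slide 3 to slide 4. Those on slide 1 lay within the range of slides 3 and 4. For slides 2, 3 and 4, slide therefore cannot be told apart from sample number.

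**Figure D3:**
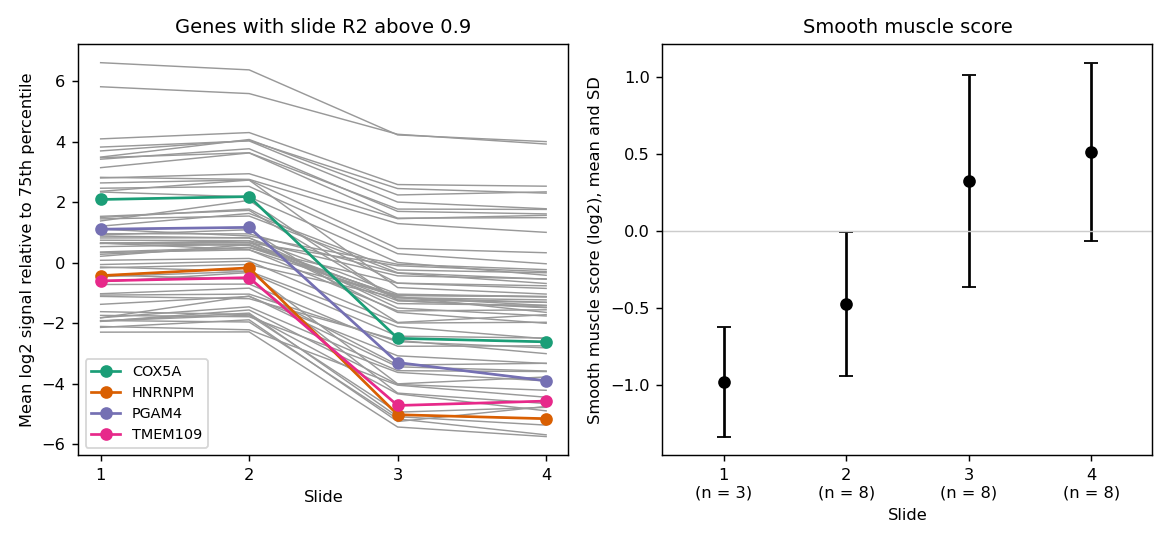
Mean log2 signal per slide relative to the 75th percentile is plotted as a line per gene for the 63 genes whose signal slide explains almost fully (left), beside the mean and SD of the smooth muscle score per slide (right). COX5A stands above 2 on average on slides 1 and 2 and below −2 on slides 3 and 4.

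Biopsies with higher epithelial scores had more signal for genes of the mature colon surface. CLCA4, a surface colonocyte gene, rose by 0.77 ± 0.16 log2 units per SD of the pan-epithelial score (SE, n = 27), AQP8 by 0.72 ± 0.15 and CD177 by 1.52 ± 0.30. C11orf86 rose by 0.69 ± 0.10, the phosphatase PTPRR by 0.68 ± 0.12, the lipocalin LCN15 by 0.85 ± 0.20, C1QTNF1-AS1 by 0.79 ± 0.16 and the elastase CELA3A by 0.74 ± 0.21 (adjusted p from 0.000104 to 0.0369 for these 8). Of 17 colonocyte genes 11 rose, 15 adjusted over the list alone, among them the guanylin hormones GUCA2B and GUCA2A, named after their values were seen. Drug and bile acid handling followed with 3 of 15 (5 adjusted over the list alone): the exporters ABCG2 and ABCB1 and the bile acid exporter subunit SLC51B. The chemokine CXCL3 fell by 0.82 ± 0.21 as the only acute inflammation gene (3 adjusted over the list alone), and the endothelial regulator SOX17 fell by 0.48 ± 0.13.

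Other falling genes were TBC1D24 (−0.60), CEP68 (−0.42), KLRA1P and ZKSCAN7 (−0.39 each), ZNF507 (−0.38) and FAR2P1 (−0.37), and the adjusted p of the 8 falling genes ranged from 0.0159 to 0.0342. Genes called singly in their lists were RBP2, PRSS2, MYLK and ACAT1, while OTOP2 and AVIL rose in the BEST4 and tuft list and OAS1 and IFIT2 in the interferon list (3 adjusted over the list alone). Over all genes 0 crypt base and 0 immediate early genes passed by limma, though 3 and 5 fell adjusted over the list alone. A further 17 lists, among them goblet, T and NK cell and fibroblast genes, had 0 genes past limma's threshold. In all, 768 of 15237 genes passed limma's test, 638 rising and 130 falling, with 2703 at an unadjusted p under 0.05. With normexp and quantile normalization 1420 rose and 779 fell, with the series matrix 1713 and 952, and without the 2 most extreme biopsies 83 and 3. The 8 rising genes kept their sign on slides 2, 3 and 4, and 6 of the 8 falling genes did. Without the 2 most extreme biopsies CD177 passed (adjusted p = 0.0197), while the other 7 rising genes (0.0502 to 0.521) and all 8 falling genes (0.0547 to 0.494) did not. Several slopes were as large there: per log2 unit of the score, C1QTNF1-AS1 had 5.04 (4.69 with all biopsies), SOX17 −3.90 (−2.83) and CEP68 −2.43 (−2.48), while AQP8 had 3.01 (4.28). Under both other scalings CELA3A alone of the rising genes did not pass (0.122 and 0.109). SOX17 alone of the falling genes passed there, CXCL3 did not (0.179 and 0.611), and the slope of CEP68 turned positive without passing. With probes above background on every array, CD177 had 3.02 per log2 unit (8.98 in the main fit) and did not pass (adjusted p = 0.127). With the mean of probes, TBC1D24, CEP68, ZKSCAN7, ZNF507 and FAR2P1 did not pass (0.0675 to 0.951), while CXCL3, SOX17 and KLRA1P did. ZKSCAN7 had −0.14 there (−2.31 in the main fit). With slide as a block CEP68 did not pass (0.0596).

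Ileal enterocyte and acute inflammation scores tracked few genes. With the acute inflammation score, SOCS3, an inhibitor of cytokine signalling, rose by 0.68 ± 0.11 log2 units per SD (SE, n = 27, adjusted p = 0.00705). Immediate early genes rose in 12 of 12 cases adjusted over the list alone, and epithelial inflammatory genes in 6 of 13, but 0 of either passed over all genes by limma. Metallothioneins, which bind zinc and copper, fell in 7 of 8 cases adjusted over the list alone and 0 over all genes. Adjusted over the list alone, 3 colonocyte and 2 drug handling genes fell and 2 mast cell genes rose. SOCS3 was the only gene of 15247 past the threshold (1330 at an unadjusted p under 0.05). Its slope per log2 unit of the score was 1.19, and 1.02 without the 2 most extreme biopsies, where it did not pass (adjusted p = 0.863; 0.000208 to 0.863 over all alternatives). Nor did it with the series matrix (1.14, adjusted p = 0.0985) or with probes above background on every array (0.89, adjusted p = 0.110). With the ileal enterocyte score, 0 of 15243 genes passed by limma and 1088 had an unadjusted p under 0.05. Adjusted over the list alone, 10 of 17 colonocyte genes rose and 3 of 13 enteroendocrine genes fell. Members of the ileal enterocyte list hardly went together (mean r between members 0.051). Their mean log2 signals ran from −5.42 (APOA4) to 1.67 (ANPEP), against 7.38 for the colonocyte gene CA1. The count of 0 on that score therefore says little about small bowel content. Without a filter on dim probes 4496 genes passed on that score.

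Distal colon scores fell into separate clusters of 9 and 18 biopsies, and the most widely spread members of the list were HOXD genes. The 9 biopsies had scores from −2.46 to −0.33 and the 18 from 0.15 to 1.01. The positional genes HOXD13, HOXD10 and HOXD11 had the largest SDs of the list, while the tight junction gene CLDN8 had one of 0.60. The members HOXB13, PRAC1 and HOXA13 were well above background on all 27 arrays. Their log2 signals were 4.60 ± 0.55, 4.06 ± 0.33 and 1.32 ± 0.24 (SD, n = 27). Low scores therefore do not mean that distal colon genes were absent. Without HOXD13 the mean r between members was 0.247, with values from −0.333 to 0.968. The 2-component model was preferred by 11.04 BIC units, just past the limit of 10. Within the clusters 0 genes tracked the score by limma, with 419 and 550 at an unadjusted p under 0.05. The clusters did not separate by that limit with normexp and quantile normalization (7.2), the series matrix (7.99), no filter on dim probes (6.46), probes above background on every array (3.17), z scores (3.57), or without HOXD13 (2.70). Nor did they without the 2 biopsies farthest from the median (8.02) or without 3 doubted arrays (8.24). With normexp and quantile normalization 66 genes passed over all biopsies, 41 rising and 25 falling. There, in a fit chosen after its values were seen, the hindgut hormone INSL5 rose by 0.98 per SD and HOXD9 by 0.97, while the amino acid carrier subunit SLC3A1 had −0.78 and SLC51A −0.71.

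**Figure D4:**
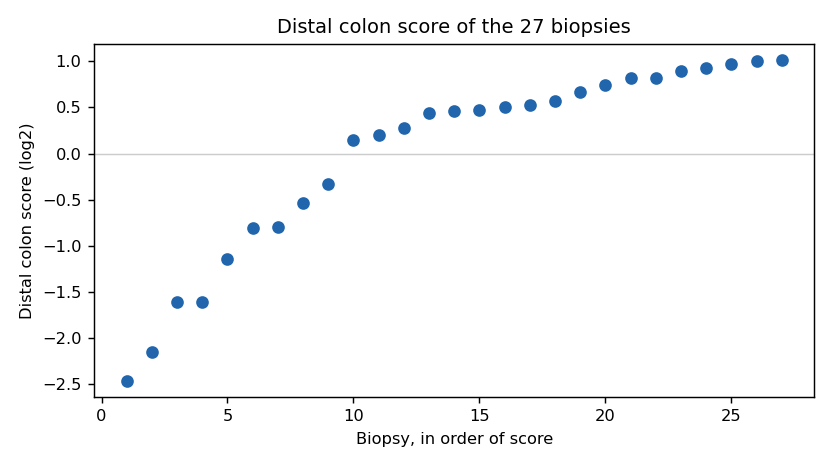
Distal colon scores of the 27 biopsies, in log2 units, are plotted from lowest to highest with a point per biopsy. Clusters of 9 and 18 biopsies lie on either side of a gap of 0.48, and the widest gap, 0.54, lies within the cluster of 9.

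Biopsies with higher B cell follicle scores had more signal for FDCSP and for some T and NK cell genes. The score had r of −0.552 with array signal and −0.617 with the share of probes above background. FDCSP, secreted by follicular dendritic cells, rose by 2.41 ± 0.22 log2 units per SD of the score (SE, n = 27). The toll-like receptor TLR10 rose by 1.37 ± 0.12, the lymphotoxin subunit LTB by 1.20 ± 0.13, the iron-binding LTF by 1.20 ± 0.11, CCL23 by 1.66 ± 0.28, RIPOR2 by 1.15 ± 0.17, the cannabinoid receptor CNR2 by 1.07 ± 0.12 and RASGRP2 by 1.06 ± 0.09 (adjusted p from 7.52e-09 to 0.000308 for these 8). Among T and NK cell genes 12 of 21 rose (13 adjusted over the list alone), including CD3G by 0.67 and the kinase LCK by 0.54. IBD drug targets JAK3, IL23A, TNF and PDE4B rose (4 of 17, and 4 adjusted over the list alone). With array signal as a covariate 5 T and NK cell genes and 3 IBD drug targets passed, and given probes above background 3 and 1. Adjusted over the list alone, 11 and 4 passed with either covariate. The monocyte chemokines CCL13 and CCL8 fell by 1.09 ± 0.23 and 0.81 ± 0.18.

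Further falling genes were PROM1 (−0.56), FBN2 (−0.48), PIGW (−0.46), ZSCAN31 (−0.45) and CENPV (−0.44), and the adjusted p of the 8 steepest falling genes ranged from 0.00288 to 0.0407. Among mitochondrial fuel use genes 3 of 11 fell (4 adjusted over the list alone): PDK4, HADHA and PPARGC1A, and 0 with either covariate. KRT19, FCGBP, ITGAX, CMA1, GBP5 and ALAS2 rose and HSPA8 fell as the only members called in their lists. With either covariate 0 of these genes passed over all genes. The genes named from lists here and above, beyond the rule, were chosen after their values were seen. In 18 lists 0 genes passed limma's threshold, though 2 plasma cell genes rose adjusted over the list alone. In all, 987 of 15239 genes passed limma's test, 470 rising and 517 falling, with 3715 at an unadjusted p under 0.05. With array signal as a covariate 136 rose and 11 fell (96 passed given probes above background), and none of the 8 steepest falling genes passed. Of the genes called with the score alone, 135 of the 470 rising and 3 of the 517 falling ones were still called. CCL13, CCL8 and PROM1 kept most of their slopes with larger SEs: −1.05 ± 0.28 for CCL13, −0.69 ± 0.22 for CCL8 and −0.52 ± 0.20 for PROM1, while CENPV had −0.23 ± 0.08. All 8 named rising genes still passed there (highest adjusted p 0.00202). Without the 2 most extreme biopsies 106 rose and 2 fell, and within clusters under normexp and quantile normalization 252 rose and 53 fell. On slides 2, 3 and 4, 8 of 8 steepest rising and 7 of 8 steepest falling genes kept their sign.

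**Figure D5:**
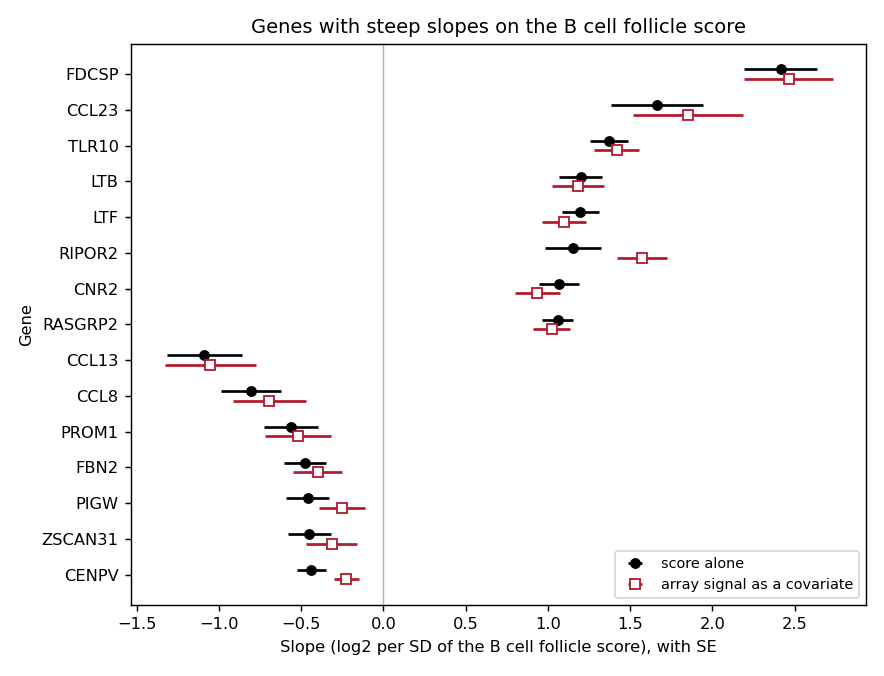
Slopes per SD of the B cell follicle score, in log2 units with SE, are plotted for the genes named in the text with the score alone (black) and with array signal as a covariate (red). With the score alone FDCSP has the largest, 2.41, and CCL13 the lowest, −1.09.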

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

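Signal outside the gene comparisons was found in probes that the comparisons do not use. Of 8263 lincRNA probes, which carry no gene symbol here, 4253 were well above background on at least 14 of the 27 arrays, and 1869 on every array. Of 96 probes for ERCC control RNAs, 10 were well above background on at least 14 arrays, while the negative control probe was above background in 0.361% of its spots. The labels do not say whether ERCC RNA was added.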

How the results depend on the processing

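No paired analysis was possible because all biopsies form a single group and carry no pairing. The alternatives without 3 doubted arrays, without each slide, with slide means removed from the SDs and with array signal as a covariate were chosen after the data were seen. Of the main results, 56 values moved by less than 1.5 times and 41 by more. The cause was not tested unless stated. With normexp and quantile normalization, genes with SD above 1 numbered 124, list pairs 28 and genes tracking the pan-epithelial score 2199. There the ileal enterocyte score tracked 2, the distal colon score 66, the acute inflammation score 0 and the B cell follicle score 305. With the series matrix these were 286, 32, 2665, 4, 63 and 0 for the first 6. The count of 305 came from within clusters. The acute inflammation score also passed the limit of 10 BIC units for clusters with normexp and quantile normalization (11.2) and without a filter on dim probes (16.5). Without a filter on dim probes, 2197 genes had an SD above 1, and 4496, 92, 3 and 2422 tracked the ileal enterocyte, distal colon, acute inflammation and B cell follicle scores. With probes above background on every array, which leaves fewer genes, 208 had an SD above 1, and 16 and 8 tracked the distal colon and acute inflammation scores. With the mean of probes 5 tracked acute inflammation, and with z scores 46 tracked the distal colon score and 3 acute inflammation. Without the 2 biopsies farthest from the median, 86, 90, 0 and 108 tracked the pan-epithelial, distal colon, acute inflammation and B cell follicle scores. Without the 3 doubted arrays, 79, 2 and 129 tracked the distal colon, acute inflammation and B cell follicle scores. With array signal as a covariate, 3961 genes differed between slides, and 1200, 2 and 147 tracked the pan-epithelial, acute inflammation and B cell follicle scores. Given the number of probes above background 96 tracked the B cell follicle score, given slide 1569, and given the pan-epithelial score 2 tracked acute inflammation. Centring scores within slides gave 26 list pairs. Slide calls numbered 606 without slide 2 and 1251 without slide 4. In the distal colon score the 2-component model was no longer preferred by 10 BIC units wherever genes were called, so those fits ran over all biopsies.

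For the 16 list pairs, 140 alternative values kept their call and 20, over 9 pairs, kept direction only. For named slopes 301 kept their call, 69 kept direction only and 4 turned. These 4, for genes falling on the pan-epithelial score, were, as slopes per log2 unit of the score, CEP68 at 0.10 (normexp and quantile) and 0.67 (series matrix) from −2.48, and, with the series matrix, ZKSCAN7 at 0.054 from −2.31 and ZNF507 at 0.082 from −2.23, with adjusted p from 0.509 to 0.959. SDs of the 25 most variable genes moved by more than their own SE in 41 cases and not in 9 under the other scalings. With normexp and quantile normalization they ranged from 0.67 (MKRN7P) to 2.57 (UGT2B15). Between 55.1% and 79.0% of spots per array were well above background, which limits what can be said of dim genes.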

Other observations

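Some genes listed for the epithelium that covers lymphoid follicles rose with the B cell follicle score. Whole biopsies cannot tell whether their signal came from that epithelium or from other cells. Of 9 genes of M cells and follicle-associated epithelium, all detected in this mucosa, UBD, a ubiquitin-like modifier, rose by 0.97 ± 0.25 log2 units per SD of the B cell follicle score (SE, n = 27) adjusted over the list alone. TNFAIP2, ICAM1 and the M cell regulator SPIB rose by 0.29, 0.27 and 0.28 adjusted over the list alone. Over all genes UBD, TNFAIP2 and ICAM1 passed limma's test too, and SPIB did not (adjusted p = 0.0525). The M cell receptor GP2 had −0.15 and the chemokine CCL20 0.21, and neither passed. MARCKSL1 (−0.07), TNFRSF11A (0.02) and TNFRSF11B (0.0029) did not pass either, so 5 of 9 did not. SOX8, a regulator of M cell maturation chosen after its values were seen, rose by 1.05 ± 0.09.

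HOXD genes went together inside the larger distal colon cluster. Among its 18 biopsies HOXD13 correlated with HOXD11 (r = 0.649, rho = 0.595, permutation p 0.00425 and 0.0103, adjusted p of r 0.0127). It correlated with HOXD9 (r = 0.595, rho = 0.637, permutation p 0.0106 and 0.00568, adjusted 0.0160) and with HOXD10 (r = 0.554, rho = 0.513, permutation p 0.0184 and 0.0312, adjusted 0.0184). Without the 2 biopsies farthest from the median, r was 0.569, 0.60 and 0.508 for these 3 relations. These relations were chosen after the clusters were seen.

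The tests of slide and of a single aberrant probe for the distal colon score, the tests of brightness run separately on rising and falling follicle genes, and the interval for second probes, were chosen only after the results were seen. Beyond different tissue or RNA on the slides, no biological explanation was tested for the slides or the distal colon clusters, since segment and donor are not given.

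Slide separated 2582 genes, while the highest of 99 random assignments of arrays to slides gave 26, so chance is excluded (1 of 100 as large). Brightness of the arrays does not account for it, as 99.3% of these genes were still called with array signal as a covariate. Different tissue or RNA on the slides stays open for these genes, since second probes followed the slide means with a median r of 0.534 against 0.266 for uncalled genes. For the genes that slide explains almost fully, spots lay no closer than random ones (percentile 93 of distance), which argues against a local flaw. Different tissue is argued against for the 12 of them with a second probe. Slide explained a median of 0.148 of the variance of these second probes (95% interval 0.083 to 0.406). The median over all genes was 0.175, and 1 of the 12 second probes exceeded 0.5. For the genes without a second probe, different tissue stays open. An order by sample number is argued against for the 63 of these slide-bound genes that could be named. All 63 were higher on slides 1 and 2 than on slides 3 and 4. Yet sample numbers of the 3 arrays on slide 1 lay within the range of slides 3 and 4. The labels name no print lot or labelling run, so these were not tested.

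The distal colon clusters were not explained by slide, which accounted for 0.0571 of the score's variance. HOXD13 correlated with HOXD10 inside the larger cluster (r = 0.554), so its probe was not unrelated to that HOXD gene there. That test covers only the 18 biopsies of the larger cluster and not the split from the other 9. A single aberrant probe therefore stays open for the split. Brightness of the arrays stays open: the score's r with array signal was −0.268 (rho = −0.294, permutation p 0.176 and 0.138), with a 95% interval from −0.588 to 0.125. The clusters rest largely on HOXD13, since without it the preference was 2.70 BIC units.

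The B cell follicle score tracked 987 genes, against at most 2 in 99 permuted scores, so chance is excluded (1 of 100 as large). A lower share of epithelium stays open. The pan-epithelial score had a slope of 0.0025 ± 0.0230 (SE) per log2 unit of the follicle score, so it showed no fall. That score is relative to each array's own signal level, and the follicle score had r of −0.552 with array signal. A flat relative score therefore cannot decide on the share of epithelium. T and NK cell minus fibroblast scores had a slope of 0.245 ± 0.0572. That slope came from the T and NK cell score (0.224 ± 0.0418), with the fibroblast score at −0.0209 ± 0.0463. It therefore cannot decide on the share of epithelium either. Brightness of the arrays may account for some of the calls, since 13.98% were still called with array signal as a covariate. By direction, 135 of 470 rising genes were still called but only 3 of 517 falling ones. Losses can also come from wider SEs. The median slope was 72.5% of its size for rising genes (0.18 from 0.25 per log2 unit of the score). For falling ones it was 46.1% (−0.07 from −0.15), so neither set is settled. Sampling of a follicle with its covering epithelium may contribute: the M cell list's median slope lay at percentile 99.95 of random lists. However, that median is the uncalled slope of CCL20, and whole biopsies cannot place the signal in epithelium.

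On the pan-epithelial score 768 genes were called, and 2 of 100 scores, the real one included, gave as many. That share is under 0.05, but a permuted score called 910 genes, more than the real one, so the count alone is weak evidence. Random list pairs of matched size had an unadjusted p under 0.05 in 25.9% of cases, against 16.5% of the pairs tested, so the relations between lists are no more frequent than those of genes in general.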
